A study of Arabidopsis thaliana with 6 samples.

How the data were processed

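RNA-seq of ribosomal RNA-depleted total RNA was available for 6 libraries of 14-day-old Arabidopsis seedlings, 3 wild type and 3 atrx-1, grouped by the genotype that the labels give, with replicate numbers taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol and depleted with a plant ribosomal RNA removal kit, and libraries were prepared with a further ribosomal RNA removal chemistry. Per the submitters' processing notes, CASAVA 1.8.2, TopHat2 2.0.14, Bowtie2 2.1.0, HTSeq 0.6.1, DESeq2 1.6.3 and DESeq were used with the genome build TAIR10. The notes give no roles or order, and gene annotation version, strand setting and treatment of reads with several matches are not given in the sources used here.

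A single table deposited by the authors held 23640 features. Per the file headers, the authors gave raw read counts per gene for each library, and these whole-number counts were the input of every test. The authors also deposited, per the file headers, a normalized signal per library, which the values show to be the count divided by 1 size factor per library, and the same signal divided by gene length in kb. The ratio of both signals gave the gene length used here, in nt, and 0.5 nt steps occur. The authors' log2 fold change, p-value and adjusted p-value of mutant against wild type were taken from their table as deposited, and they are blank for all organelle features. A p-value was given for 23316 features and an adjusted p-value for 6995. Coordinates and biotypes are those of the table. Of the identifiers, 23391 matched a locus tag of the reference annotation TAIR10.1 and 249 did not. Only 13.3% of the matched genes had the same start and end in both, so TAIR10.1 was used only for names and for which genes overlap. Some gene names in the table had been turned into dates and were replaced by the gene identifier. No column of per-sample values was left unmapped, and every feature row named a gene.

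Library totals ranged from 936243 to 14001726 counts. At these depths between 6.78% and 25.5% of the features had a count of 0 in a library, and 597 features had a count of 0 in all 6. The Wilson 95% interval of the chloroplast share was narrow, for instance 59% to 59.2% in the shallowest library, and covers counting error only, since no molecular identifiers are described. No 2 libraries were copies: the closest pair, mutant libraries 1 and 2, still differed by a mean chi-square of 2.29 per gene over 16638 genes, where sampling noise alone gives 1. The wild-type libraries were less alike. By this measure, which also depends on depth, wild-type library 2 differed from wild-type libraries 1 and 3 by 10.8 and 4.71. It differed from mutant libraries 1, 2 and 3 by 3.63, 3.08 and 3.03. Its Spearman correlation was highest with wild-type library 3 (0.877) and lowest with wild-type library 1 (0.757).

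Differential expression was tested with edgeR 4.0.16 in R 4.3.3 on the deposited counts, with TMM scaling, the default filterByExpr filter (minimum count 10, minimum total 15), glmQLFit and glmQLFTest with genotype as the only term, and Benjamini-Hochberg adjustment with a threshold of 0.05. The filter kept 13819 features and removed 9821. The biological coefficient of variation was 19.3%. Standard errors were derived from the quasi-likelihood F statistic. CPM values are counts scaled to a common library total after TMM scaling. Shares and slopes of single libraries were compared by an exact two-sided permutation test of the difference in means. Gene sets were tested with camera at a preset correlation of 0.01, adjusted over the 21 lists and classes with at least 3 tested members. The 20 lists covered histone H3 genes, histone chaperones, SNF2 remodelers, DNA methylation and silencing machinery, ribosome biogenesis, DNA damage, cell cycle, nuclear photosynthesis, flowering time, circadian clock, salicylic acid and immunity, jasmonate, heat shock, cold and drought, flavonoids, glucosinolates, root, floral, and seed markers, and genes reported as silenced by DNA methylation. The classes were transposable element, chloroplast and mitochondrial genes, with nuclear ribosomal RNA features given as counts only. The floral list and the silenced list each had 1 tested member and no set test.

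The lists, the tests and the rule for named genes were fixed before the data were examined. The rule named ATRX, then, among genes past the threshold with a mean of at least 2 CPM and no overlap between groups, the 8 with the largest and the 8 with the smallest log2 fold change. From each list it took up to 4 members past the threshold, or else the member with the smallest p. List members outside this rule, small-RNA features, genes of annotation terms and AT2G13146 were named after their values had been seen.

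Alternatives fixed beforehand were DESeq2 1.42.0, RLE size factors, nuclear genes only, no low-count filter, a stricter filter (mean of at least 5 CPM, and 1 CPM in every library of a group), the replicate number as a block, leaving out each library in turn, camera with an estimated correlation, and fry. Alternatives added after seeing the data were a gene-length correction, alone, with each library left out, and with DESeq2, and voom with sample quality weights in limma 3.58.1. The correction fitted, for each library, a loess curve (span 0.5, degree 1) of the log2 deviation from the gene mean on log length over nuclear genes with a mean log2 CPM above 3, and used it as an offset. It covers nuclear genes only and removes any true genotype difference that follows gene length as well as a technical one.

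The procedure was tested on simulated data drawn from the real means, library sizes and dispersions of this comparison, with 200 changed genes. Without a length trend, edgeR recovered 36% of 2-fold and 91% of 4-fold changes over 13039 tested genes and called 10 unchanged genes. With the observed length trend imposed, it recovered 45% and 97% over 13332 tested genes and called 124 unchanged genes, and with the length correction it recovered 41% and 95% over 13208 tested genes and called 18. The simulation gave each gene 1 dispersion for all libraries. In the real data the mean chi-square per gene was 4.71 to 10.8 between wild-type libraries and 2.29 to 3.5 between mutant libraries. The real edgeR fit called only 16 genes in all, so recovery in the real data may be lower. Of 20 random gene lists 0 were called by camera in these simulations, and the planted list was called in each. Genes were drawn independently and random lists without regard to length. The simulations therefore cannot show how camera behaves with correlated genes or with lists of mostly long or short genes. Plots were drawn with matplotlib 3.10.9.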

Results

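RNA was profiled in 14-day-old Arabidopsis thaliana seedlings of the Col ecotype that had been grown in vitro. The 6 libraries fell into 2 groups of 3, wild-type plants and plants carrying atrx-1, a mutant allele of ATRX. ATRX is a SNF2-type chromatin remodeler that, in animals and plants, takes part in the deposition of the histone variant H3.3. Total RNA was depleted of ribosomal RNA before sequencing, so that transcripts without a poly(A) tail were also counted. The table of gene counts held 23640 features. Wild-type libraries 1, 2 and 3 contained 3475037, 936243 and 3624088 counts, and mutant libraries 1, 2 and 3 contained 14001726, 3906126 and 2887834 counts. Chloroplast-encoded genes took 58.8% ± 3.19 (SD, n = 3) of the counts in the wild type and 58.2% ± 1.25 (SD, n = 3) in the mutant, which left between 371706 and 5635309 nuclear counts per library. The group difference in the chloroplast share was within the spread between libraries (exact two-sided permutation test, p = 0.9). With 3 libraries per group the smallest p such a test can give is 0.1. No label states that the replicates were separate cultures, so all p-values measure the spread between these samples, which may be technical.

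The single comparison that the design implies, mutant against wild type, addresses how steady-state RNA in seedlings differs when ATRX is disrupted. The targeted gene itself was examined first. ATRX (AT1G08600, TAIR10 chromosome 1, 2723824 to 2733613, protein-coding) was at 5.38 ± 0.529 CPM (counts scaled to a common library total; SD, n = 3) in the wild type and 1.29 ± 0.598 CPM (SD, n = 3) in the mutant, 4.25-fold lower. Every mutant library lay below every wild-type library. The counts behind these values were small, at 16, 5 and 18 reads in wild-type libraries 1, 2 and 3 and 18, 3 and 6 reads in mutant libraries 1, 2 and 3. The log2 fold change was -2.09 ± 0.38 (SE) and the edgeR adjusted p was 0.0536, which missed the threshold of 0.05, while the unadjusted p was 0.000125. The edgeR adjusted p was 0.0343, 0.0587 and 0.0708 without wild-type library 1, 2 and 3, and 0.326, 0.321 and 0.107 without mutant library 1, 2 and 3. Where in the gene atrx-1 is disrupted is not given in the sources used here, and reads from the remaining parts can persist. In the reference annotation ATRX overlaps the neighbouring gene AT1G08610. In the authors' deposited table ATRX had a log2 fold change of -1.29 with p = 6.27e-05 and no adjusted p. How the authors' fold changes were estimated is not given in the sources used here. The sizes of -1.29 and of the edgeR value of -2.09 may therefore not be comparable.

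Transcripts of 16 genes fell in the mutant, all by at least 2-fold, and 0 genes passed the threshold in the other direction. The genes included MES1, a methyl salicylate esterase of the salicylic acid pathway, at 9.91 ± 3.79 CPM (SD, n = 3) in the wild type and 2.27 ± 0.32 CPM (SD, n = 3) in the mutant. KIN2, a cold- and abscisic acid-induced protein, went from 151 ± 37.6 to 56.5 ± 2.66 CPM (SD, n = 3 each). The metallothionein MT1C, a small cysteine-rich metal-binding protein, went from 161 ± 33.3 to 67.5 ± 0.511 CPM (SD, n = 3 each). A pair of small endoplasmic reticulum membrane proteins, the Sec61 gamma subunit of the protein translocon (AT4G24920) and the ribosome-associated protein RAMP4 (AT1G27330), were 2.32-fold and 2.74-fold lower. In all 16 genes each mutant library lay below each wild-type library.

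Among the 16 genes, the largest change was in AT5G35480, a 355 nt gene of unknown function on chromosome 5 (13689204 to 13689558), with a log2 fold change of -2.85 ± 0.34 (SE) and an edgeR adjusted p of 0.0241. AT4G23420, annotated as an NAD(P)-binding Rossmann-fold protein (chromosome 4, 12225515 to 12228718), was at 1114 ± 599 CPM in the wild type and 224 ± 62.5 CPM in the mutant (SD, n = 3 each), with a log2 fold change of -2.31 ± 0.35 (SE). A U1 small nuclear RNA gene, AT4G07120, lies within AT4G23420 in the reference annotation and has no feature of its own in the table. MES1 (chromosome 2, 10047379 to 10049291) had a log2 fold change of -2.16 ± 0.34 (SE), and the DUF581 gene AT4G17670 had -2.13 ± 0.36 (SE). Lower values were also found for the citrate synthase-related AT2G11270 (log2 fold change -1.87), the second Rossmann-fold gene AT1G66800 (-1.70) and the chitinase-family gene AT2G43590 (-1.54). RAMP4 followed at -1.45 ± 0.22 (SE) and KIN2 (chromosome 5, 5211911 to 5212665) at -1.43 ± 0.22 (SE). The remaining 7 genes were the chloroplast-encoded valine tRNA TRNV.1 (ATCG00450, log2 fold change -1.38), AT1G31835 (-1.37), AT3G09860 (-1.28), the NADH dehydrogenase subunit AT1G14450 (-1.26), MT1C (chromosome 1, 2341542 to 2342123, -1.26), AT5G64850 (-1.23) and the Sec61 subunit AT4G24920 (-1.21). KIN2 has the similar neighbour KIN1, and MT1C belongs to a family of similar genes, so the split of reads between family members is uncertain. Of the 16 genes, 5 overlap another annotated gene in the reference, and strand use in counting is not given in the sources used here.

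**Figure D1:**
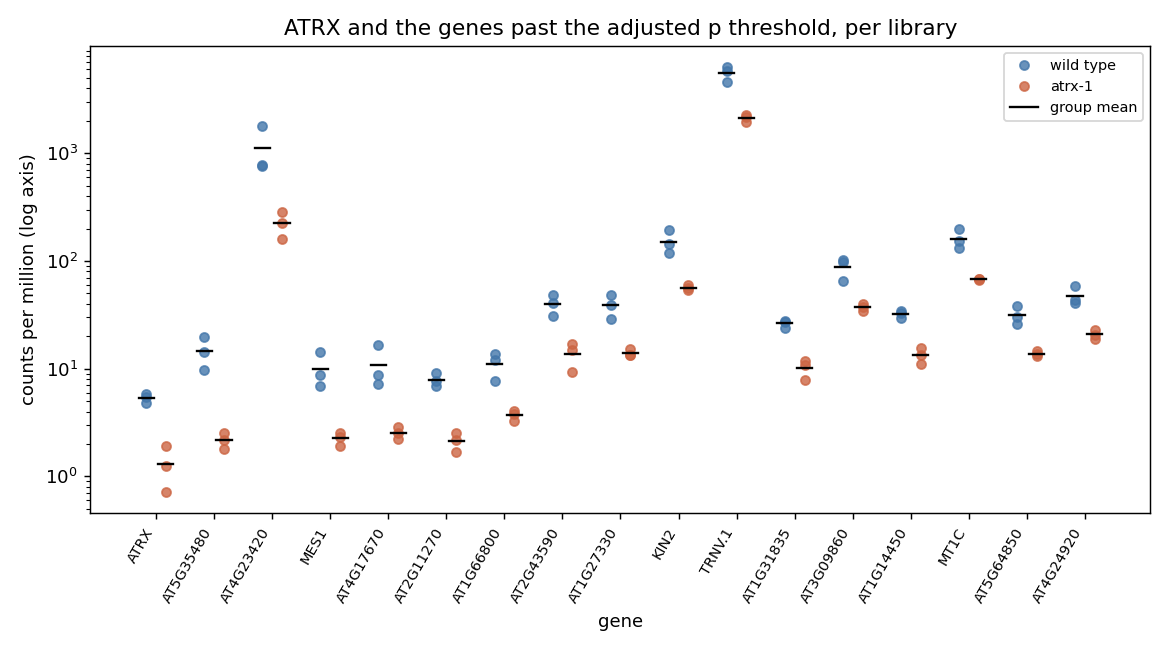
CPM (log axis) of ATRX and of the 16 genes with an edgeR adjusted p under 0.05, with 1 point per library, 3 wild-type and 3 atrx-1 libraries per gene, and a bar at each group mean. For every gene shown the atrx-1 points lie below the wild-type points, with ATRX at 5.38 CPM on average in the wild type and 1.29 CPM in the mutant.

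In edgeR's quasi-likelihood test, 13819 features were tested and 2701 had an unadjusted p under 0.05, of which 1194 were higher and 1507 lower in the mutant. DESeq2 called 211 genes, 43 higher and 168 lower, and 11 of them were among the 16. The rest of the 16 (AT5G35480, MES1, AT4G17670, AT2G11270 and AT1G66800) had no adjusted p in DESeq2, and neither had ATRX. The edgeR count was 0 without mutant library 1, 0 without mutant library 2 and 3 without mutant library 3 (1575, 1733 and 2526 genes at an unadjusted p under 0.05, and 17, 24 and 127 calls by DESeq2), whereas all 16 genes were called again without each wild-type library in turn, among 378, 104 and 119 calls. The 15 nuclear genes among the 16 were short, with a median length of 616 nt against 1556 nt over all tested nuclear genes.

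Gene length moved with genotype across the whole transcriptome. Over 13168 nuclear genes the log2 fold change had a Spearman correlation of 0.584 with gene length, calculated across genes, which are not independent replicates. When these genes were divided into 10 groups by length, the median log2 fold change was -0.49 in the group of shortest genes (median length 643 nt) and 0.42 in the group of longest genes (3625 nt). Per library, expression relative to the gene mean changed by -0.23, -0.06 and -0.17 on the log2 scale for each doubling of length in wild-type libraries 1, 2 and 3, and by 0.15, 0.16 and 0.16 in mutant libraries 1, 2 and 3. The groups did not overlap (exact two-sided permutation test, p = 0.1, the smallest the design allows). Between pairs of wild-type libraries the correlation with length was between -0.136 and 0.147. Small structured RNAs moved with the same division: snRNA and snoRNA features took 0.629% ± 0.409 (SD, n = 3) of counts in the wild type and 0.18% ± 0.0675 (SD, n = 3) in the mutant (exact two-sided permutation test, p = 0.1). Wild-type library 1 had the highest share (1.09%, Wilson 95% interval 1.08% to 1.1%), and without it the wild-type mean was 0.398%.

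**Figure D2:**
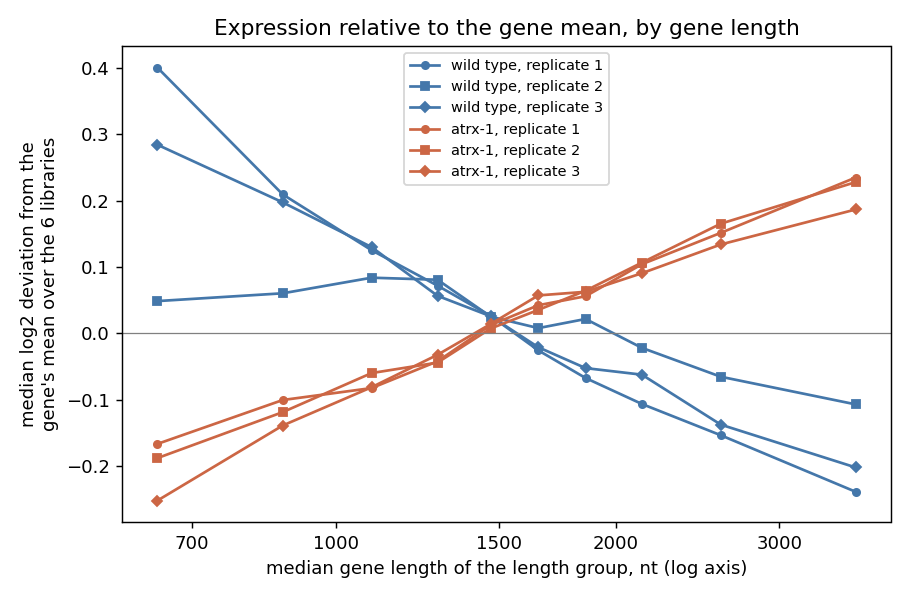
Median log2 deviation of nuclear genes from their mean over the 6 libraries (vertical axis) in 10 groups of genes of rising length (horizontal axis, log scale, median length in nt), with 1 line per library. From the group of shortest to the group of longest genes, the medians go from 0.40 to -0.24, 0.05 to -0.11 and 0.28 to -0.20 in wild-type libraries 1, 2 and 3, and from -0.17 to 0.23, -0.19 to 0.23 and -0.25 to 0.19 in atrx-1 libraries 1, 2 and 3.

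When each library's trend on length was removed, an alternative chosen after the data were seen, 4 genes passed the threshold. ATRX was then past it, with a log2 fold change of -2.60 ± 0.39 (SE) and an edgeR adjusted p of 0.0494. AT5G35480 (-2.20 ± 0.33, SE) and AT4G23420 (-2.39 ± 0.35, SE) were the 2 genes shared with the 16. The pseudogene AT2G13146 (chromosome 2, 5431033 to 5431247) was higher in the mutant, with 9.52 ± 3.60 CPM in the wild type and 16.8 ± 2.14 CPM in the mutant (SD, n = 3 each) and a length-corrected log2 fold change of 1.51 ± 0.21 (SE). This gene is 215 nt long, and without the correction it was at 0.71 ± 0.25 (SE) with an edgeR adjusted p of 0.145, so the correction made the call. With the same correction the other 13 nuclear genes of the 16 did not pass. MES1 was then at -1.90 ± 0.33 (SE), AT4G17670 at -1.82, AT1G66800 at -1.56, AT2G43590 at -1.37 and AT2G11270 at -1.14. AT1G31835 was at -0.94, AT5G64850 at -0.94, RAMP4 at -0.91 ± 0.21 (SE; edgeR adjusted p = 0.237), KIN2 at -0.90 ± 0.19 (SE), AT3G09860 at -0.84, AT1G14450 at -0.77, MT1C at -0.72 ± 0.18 (SE) and the Sec61 subunit AT4G24920 at -0.69 ± 0.18 (SE; edgeR adjusted p = 0.254). The corrected count was 22 without wild-type library 1, 70 without wild-type library 3 and 1 without mutant library 3. It was 0 without wild-type library 2, mutant library 1 or mutant library 2 (1567, 764 and 809 genes at an unadjusted p under 0.05).

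Among chromatin genes, SNF2 remodelers other than ATRX rose as a group: 12 of 13 tested members were higher in the mutant, with a median log2 fold change of 0.56 (camera, adjusted p = 0.000126). The group call was lost when the correlation between genes was estimated (adjusted p = 0.35) and after length correction (median -0.05, adjusted p = 0.748), and these genes are long, with a median of 4402 nt. Before length correction the group also passed with fry (adjusted p = 0.0234). Over all genes none of its members passed in edgeR, while BRM passed in DESeq2 (adjusted p = 0.0281), in edgeR without wild-type library 1 (adjusted p = 0.0391) and in the authors' deposited table (adjusted p = 0.0145). The authors' deposited table also called SYD, CHR5 and CHR4 as higher. In edgeR 5 members passed adjusted over the list alone. These were the SWI/SNF ATPase BRM, with 20.7 ± 3.91 CPM in the wild type and 37.7 ± 1.68 CPM in the mutant (SD, n = 3 each; log2 fold change 0.92 ± 0.19, SE), its relative SYD (0.59), CHR5 (0.77), INO80 (0.70) and the ISWI-type CHR11 (0.65). After length correction none of these passed adjusted over the list alone, with BRM at 0.33 ± 0.19 (SE), CHR5 at 0.21, SYD at -0.12, INO80 at 0.19 and CHR11 at 0.27 (adjusted p of at least 0.756). DDM1, the remodeler required for DNA methylation of heterochromatin, was the 1 member with a lower value, at -0.18 ± 0.35 (SE). Of 14 genes of the DNA methylation and silencing machinery, 12 had higher values (median 0.33, camera adjusted p = 0.0777, median length 3713 nt). The list passed without wild-type library 2 (camera adjusted p = 0.0197) and without mutant library 2 (camera adjusted p = 0.0233). The DNA demethylase DME passed adjusted over the list alone, with a log2 fold change of 0.97 ± 0.26 (SE), as the 1 such member, and after length correction it was at 0.37 ± 0.26 (SE) and did not pass (adjusted p = 0.683). Over all genes DME passed in edgeR without wild-type library 1 (adjusted p = 0.0353) and in the authors' deposited table (adjusted p = 0.0267). The median of this list was -0.12 after length correction. Histone chaperones (10 of 16 higher, median 0.28, adjusted p = 0.231) and the 8 genes of histone H3.1 and H3.3 (2 higher, 6 lower, median -0.17, adjusted p = 0.349, median length 719 nt) did not pass. With the length correction 9 of the 16 chaperones were lower (median -0.02) and 5 of the 8 H3 genes higher (median 0.14). Neither list passed then (camera adjusted p = 0.767 and 0.251). SSRP1 of the FACT complex, with a log2 fold change of 0.66 ± 0.19 (SE), and the H3.1 gene HTR13, with -0.59 ± 0.27 (SE), had the smallest p in these 2 lists, and neither list had a member past the threshold in edgeR over all genes or adjusted over the list alone. The authors' deposited table called the chaperone NAP1;2 as higher.

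Nuclear maintenance genes showed no group change past the threshold. Ribosome biogenesis genes were higher in 9 of 13 tested members (median log2 fold change 0.13, camera adjusted p = 0.231), with NRPA1, the largest subunit of RNA polymerase I, at 0.72 ± 0.24 (SE). With the length correction 8 of the 13 were lower and 5 higher (median -0.07). DNA damage response and repair genes were higher in 6 of 9 (median 0.10, adjusted p = 0.726). With the length correction all 9 were lower (median -0.19, camera adjusted p = 0.473). The checkpoint kinase gene ATM, 11880 nt long, had a log2 fold change of 0.72 ± 0.24 (SE), which was -0.034 ± 0.25 (SE) after length correction. Cell cycle and DNA replication genes were higher in 7 of 11 (median 0.08, adjusted p = 0.961), and the replication clamp gene PCNA2 was at -0.51 ± 0.28 (SE). With the length correction 8 of these 11 were lower and 3 higher (median -0.08). In these 3 lists 0 members were called over all genes by edgeR and 0 adjusted over the list alone, and NRPA1, ATM and PCNA2 had unadjusted p-values of 0.0108, 0.0116 and 0.0935.

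Nuclear photosynthesis genes were abundant and close to equal between genotypes. Of 27 tested members, 15 had higher and 12 lower values in the mutant (median log2 fold change 0.08, camera adjusted p = 0.36, and 0.0472 without wild-type library 2), and none passed in edgeR over all genes or adjusted over the list alone. The authors' deposited table called RCA, the Rubisco activase gene, as higher. The photosystem I subunit PSAF was at 432 ± 53.3 CPM in the wild type and 590 ± 24.6 CPM in the mutant (SD, n = 3 each; log2 fold change 0.45 ± 0.20, SE, edgeR adjusted p = 0.233). These genes are shorter than most (median 1107 nt), and after length correction the list rose, with 21 of 27 members higher, a median of 0.26 and a camera adjusted p of 0.00549, which was 0.82 with an estimated correlation. Most lists shared this value of 0.82, SNF2 remodelers and seed markers among them, so it does not tell the lists apart. Clock genes were higher in 14 of 16 (median 0.30, adjusted p = 0.0761, and 0.0309 without wild-type library 2, median length 2178 nt). The pseudo-response regulator PRR7 (log2 fold change 0.73 ± 0.22, SE) and the transcriptional coactivator LNK1 (0.70 ± 0.21, SE) passed adjusted over the list alone, and no clock gene passed in edgeR over all genes, while LNK1 was called as higher in the authors' deposited table. After length correction PRR7 was at 0.42 ± 0.22 (SE) and LNK1 at 0.43 ± 0.21 (SE), and neither passed adjusted over the list alone (adjusted p = 0.42 each). Of 6 flowering time genes 5 were lower (median -0.19, adjusted p = 0.231). MAF1, a floral repressor related to FLC, was 20 ± 3.13 CPM in the wild type and 12.7 ± 1.38 CPM in the mutant (SD, n = 3 each; log2 fold change -0.66 ± 0.20, SE), past the threshold in edgeR adjusted over the list alone and not over all genes. After length correction MAF1 was at -0.39 ± 0.20 (SE) and did not pass adjusted over the list alone (adjusted p = 0.304).

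In the salicylic acid and immune response list, 6 of 10 tested members were higher (median log2 fold change 0.20, camera adjusted p = 0.261, median length 2088 nt). SNC1, an intracellular immune receptor of the TIR-NBS-LRR class that sits in a cluster of similar genes, was at 36.7 ± 8.41 CPM in the wild type and 76.5 ± 5.48 CPM in the mutant (SD, n = 3 each). Its log2 fold change was 1.03 ± 0.21 (SE) with an edgeR adjusted p of 0.0582, 0.00265 adjusted over the list alone, and in the authors' deposited table its adjusted p was 0.000696. SNC1 passed over all genes in DESeq2 (adjusted p = 0.00328) and in edgeR without wild-type library 1 (adjusted p = 0.0324) or 3 (adjusted p = 0.0386). After length correction SNC1 was at 0.60 ± 0.20 (SE) and did not pass adjusted over the list alone (adjusted p = 0.0556). Cold, drought and abscisic acid genes were split, with 8 of 15 lower (median -0.02, adjusted p = 0.5). KIN2 was called over all genes in edgeR, DESeq2 and the authors' deposited table, which also called RAB18 as higher. Adjusted over the list alone 4 members were lower, KIN2, KIN1, the dehydrin ERD10 and COR15B, and 1 was higher, the abscisic acid signalling phosphatase HAB1. After length correction KIN2 (adjusted p = 0.005) and ERD10 (adjusted p = 0.0416) still passed adjusted over the list alone, and KIN1, COR15B and HAB1 did not (adjusted p = 0.253 each). The dehydrin RAB18 then passed as higher (log2 fold change 0.995 ± 0.29, SE; adjusted p = 0.0294). Jasmonate genes were lower in 9 of 12 (median -0.31, adjusted p = 0.261), with no member past either threshold in edgeR. The vegetative storage protein VSP2 was at -0.75 ± 0.30 (SE), with 34.9, 102 and 66.8 CPM in wild-type libraries 1, 2 and 3 and 35.2, 42.5 and 38.9 CPM in mutant libraries 1, 2 and 3, so the groups overlapped. With 1 library left out VSP2 ranged from -1.07, past the threshold without wild-type library 1 (edgeR adjusted p = 0.0221), to -0.42. In the authors' deposited table its adjusted p was 0.00284. Of 4 heat shock genes 2 were higher and 2 lower (median 0.19, adjusted p = 0.722). Adjusted over the list alone, the coactivator MBF1C was lower (-0.59 ± 0.21, SE) and the chaperone HSP90.1 was higher (0.71 ± 0.26, SE). After length correction neither passed, with MBF1C at -0.13 ± 0.21 (SE; adjusted p = 0.712) and HSP90.1 at 0.45 ± 0.26 (SE; adjusted p = 0.437). No heat shock gene passed over all genes in edgeR, DESeq2 or the authors' deposited table.

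Secondary metabolism lists did not pass. Flavonoid and anthocyanin genes were lower in 7 of 8 (median log2 fold change -0.31, camera adjusted p = 0.261, and 0.0203 without mutant library 3), and the flavonol synthase FLS1 was at -0.98 ± 0.28 (SE), past the threshold adjusted over the list alone before (adjusted p = 0.0345) and after length correction (adjusted p = 0.0464). Glucosinolate genes were lower in 12 of 19 (median -0.09, adjusted p = 0.261), with no member past either threshold in edgeR. AOP2, which has the biotype pseudogene, was at -0.89 ± 0.28 (SE).

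**Figure D3:**
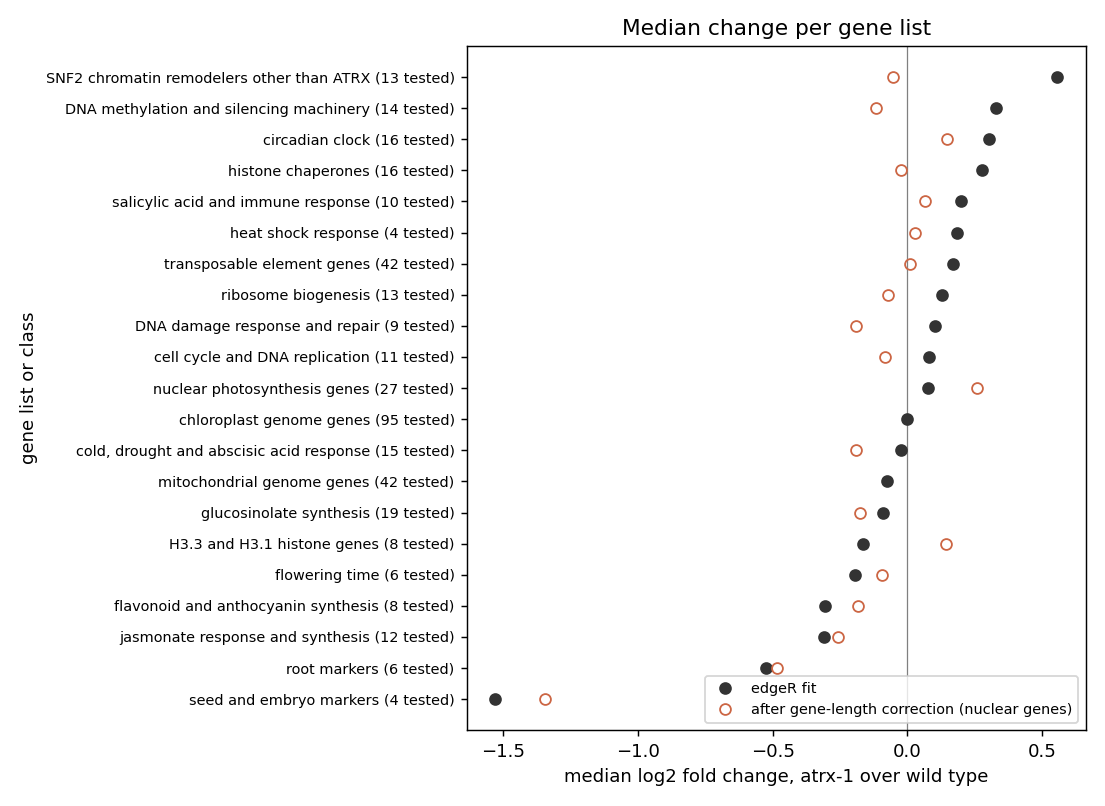
Median log2 fold change, atrx-1 over wild type (horizontal axis), of the tested members of each gene list or class (vertical axis), in the edgeR fit (filled points) and after gene-length correction of nuclear genes (open points). The SNF2 remodelers move from 0.56 to -0.05 with the correction, and the seed and embryo markers from -1.53 to -1.35.

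Tissue markers were included because whole seedlings were sampled. Seed and embryo markers fell as a group: all 4 tested members were lower in the mutant, with a median log2 fold change of -1.53 (camera adjusted p = 0.000178). The adjusted p was 0.467 with an estimated correlation. After length correction the median was -1.35 (camera adjusted p = 1.24e-05, and 0.82 with an estimated correlation, a value that most lists shared). The members were the storage globulins CRA1 (53.3 ± 22.7 CPM in the wild type, 22.9 ± 8.82 CPM in the mutant; SD, n = 3 each) and CRC, and the oil body proteins OLEO1 and OLEO2 (9.71 ± 3.94 and 4.02 ± 1.02 CPM; SD, n = 3 each). All 4 passed adjusted over the list alone and 0 passed in edgeR over all genes, where their unadjusted p-values lay between 0.000824 and 0.0116, while DESeq2 called 1, CRA1 (adjusted p = 0.032). OLEO2 passed in edgeR without wild-type library 2 (adjusted p = 0.0444). Without wild-type library 1 the median was -0.90. Root markers were lower in 4 of 6 (median -0.53, adjusted p = 0.231). The root hair expansin EXPA18 (-1.07 ± 0.31, SE) and the Casparian strip protein CASP1 (-0.86 ± 0.30, SE) passed in edgeR adjusted over the list alone and not over all genes. After length correction EXPA18 was at -0.87 ± 0.32 (SE; adjusted p = 0.101) and CASP1 at -0.57 ± 0.32 (SE; adjusted p = 0.268), and neither passed adjusted over the list alone. Of the floral markers only SEP4 had enough reads to be tested, at 9.17 ± 2.23 CPM in the wild type and 9.45 ± 1.54 CPM in the mutant (SD, n = 3 each).

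Of 375 transposable element genes 42 had enough reads to be tested, 32 with higher values (median log2 fold change 0.17, camera adjusted p = 0.0777, and 0.0225 without wild-type library 2, median length 2633 nt), and after length correction the median was 0.01. The element gene AT1G20390 (chromosome 1, 7065494 to 7071561) was at 1.19 ± 0.277 CPM in the wild type and 4.63 ± 0.651 CPM in the mutant (SD, n = 3 each), with a log2 fold change of 1.94 ± 0.41 (SE) and an edgeR adjusted p of 0.0597. This gene had few reads, at 5, 1 and 3 in wild-type libraries 1, 2 and 3 and 78, 17 and 14 in mutant libraries 1, 2 and 3. It was the 1 element that passed adjusted over the class alone, and after length correction it did not (log2 fold change 1.37 ± 0.42, SE; adjusted p = 0.136). After length correction the element gene AT3G42806 passed adjusted over the class alone in the other direction (-1.37 ± 0.33, SE; adjusted p = 0.0421), with 68.8 ± 39.7 CPM in the wild type and 38.2 ± 8.32 CPM in the mutant (SD, n = 3 each). The 1 testable gene among those reported as silenced by DNA methylation, QQS, a regulator of starch and protein content, was at 1.29 ± 1.73 CPM in the wild type and 3.80 ± 0.702 CPM in the mutant (SD, n = 3 each; edgeR adjusted p = 0.252, and 0.0485 adjusted over the list alone, where it is the only tested member), and the groups overlapped.

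Chloroplast genes were lower in 48 and higher in 47 of 95 tested (median log2 fold change -0.0021, camera adjusted p = 0.261, and 0.00155 as lower without mutant library 1), and TRNV.1 (5569 ± 885 CPM in the wild type, 2136 ± 157 CPM in the mutant; SD, n = 3 each) was the 1 member called over all genes in edgeR. DESeq2 called 5 as higher and 8 as lower. Adjusted over the class alone, 6 were higher and 10 lower. The 10 lower members were 71 to 159 nt long, and the higher ones were 711 to 2253 nt long except TRNS.2 (92 nt). Organelle genes were not length-corrected, so these calls cannot be told apart from the length trend. Mitochondrial genes were lower in 24 of 42 (median -0.07, adjusted p = 0.5), and the ATP synthase subunit gene ATP9, the member with the smallest p, was at 1365 ± 361 CPM in the wild type and 724 ± 46.7 CPM in the mutant (SD, n = 3 each; log2 fold change -0.92 ± 0.23, SE; edgeR adjusted p = 0.0782, and 0.0421 without wild-type library 1). DESeq2 called ATP9 (adjusted p = 0.00392) and NAD9 as lower. Nuclear ribosomal RNA features, targets of the depletion, were low except in mutant library 3. The 18S feature AT3G41768 had 449, 85 and 52 counts in wild-type libraries 1, 2 and 3, and 162, 188 and 10417 counts in mutant libraries 1, 2 and 3. The other 18S feature, AT2G01010, had at most 23 counts per library, and the 5.8S features AT2G01020 and AT3G41979 had at most 16 and 17.

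The authors' deposited table called 494 nuclear genes at an adjusted p under 0.05, 214 higher and 280 lower in the mutant. In the authors' deposited table the higher genes had a median length of 2570 nt and the lower genes 761 nt. Of the 16 genes called by edgeR, 10 have an adjusted p in the authors' deposited table and 9 of those are below the threshold there. The authors' deposited table gives MT1C an adjusted p of 2.97e-08 and KIN2 0.000484. The log2 fold changes in the authors' deposited table had a Spearman correlation of 0.519 with gene length across genes.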

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

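The length correction, DESeq2 with that correction, the corrected fits with 1 library left out, and voom with sample quality weights were chosen after seeing the data. The main edgeR fit gave 16 genes, 0 higher and 16 lower, all at least 2-fold. DESeq2 gave 211 (43 higher, 168 lower, 107 at least 2-fold), and 15641 features had no adjusted p there. RLE size factors gave 38 (2 higher, 36 lower, 34 at least 2-fold), no low-count filter 592 (192, 400, 365), voom with quality weights 887 (317, 570, 350), the length correction 4 (1, 3, 4), and DESeq2 with length correction 3 higher and 9 lower. Nuclear genes only and the stricter filter stayed within 1.5 times of the main counts. Leaving out 1 library gave 0 to 378 genes, 0 to 168 higher, 0 to 210 lower and 0 to 179 at least 2-fold, and with length correction 0 to 70. Each library changed the edgeR count by more than 1.5 times: 378, 104 and 119 genes without wild-type library 1, 2 and 3, and 0, 0 and 3 without mutant library 1, 2 and 3. ATRX kept its direction in every fit. It passed the threshold with RLE size factors (log2 fold change -2.11), no filter (-2.04), length correction (-2.60), DESeq2 with length correction (-2.61) and voom (-2.25), and lay between -2.27 and -1.89 with 1 library left out. The replicate block gave 34 genes, 34 lower and 34 at least 2-fold. Whether the shared replicate numbers pair the samples stays undecided. Over 2091 genes, deviations from the group mean correlated at 0.139, 0.349 and -0.173 between libraries of the same number. Wild-type libraries 1 and 2 correlated best with the mutant library of their number, library 1 narrowly (0.131 with mutant library 3). Wild-type library 3 correlated best with mutant library 2 (0.176). Deviations from a mean of 3 libraries depend on each other, so these correlations cannot exclude a shared batch. The cause of these differences was not tested, except that fewer libraries or more features entered some fits by construction.

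Gene list adjusted p-values changed as follows. With an estimated correlation camera called 0 lists, where SNF2 remodelers were at 0.35 and seed markers at 0.467. With fry, seed markers were at 0.164, SNF2 remodelers, higher, at 0.0234 and flowering time genes, lower, at 0.00729. Length correction ended the call of SNF2 remodelers (0.748) and added nuclear photosynthesis genes (0.00549). Under it the direction that camera gives turned for histone H3 genes (0.251), DNA methylation machinery (0.748), DNA damage genes (0.473) and cell cycle genes (0.748), none of them called in either fit. Without a low-count filter the DNA methylation machinery passed (0.00673), and uncalled cell cycle genes (0.909) and mitochondrial genes (0.679) changed direction, as did cell cycle genes with the stricter filter (0.715). With 1 library left out, between 2 and 6 lists were called. The adjusted p ranged from 0.000125 to 0.000616 for SNF2 remodelers, 3.28e-06 to 0.0289 for seed markers, 0.0197 to 0.149 for DNA methylation machinery, 0.0472 to 0.551 for nuclear photosynthesis, 0.0309 to 0.296 for clock genes, 0.0225 to 0.245 for transposable elements, 0.00155 to 0.724 for chloroplast genes and 0.0203 to 0.459 for flavonoid genes. It ranged from 0.41 to 0.938 for cell cycle genes, 0.323 to 0.959 for cold and drought genes, 0.458 to 0.881 for DNA damage genes and 0.356 to 0.938 for mitochondrial genes, which changed direction in at least 1 of these fits without a call. The cause was not tested. Among named genes, SEP4 changed sign with RLE size factors (-0.020) and voom (-0.12) and ranged from -0.16 to 0.24 with 1 library left out, and ATM changed sign with length correction (-0.034, and -0.00014 with DESeq2). With length correction ATRX gained the threshold, and of the 35 other named genes with a corrected value 21 kept their direction and side of the threshold, 13 lost the threshold and 1 reversed. The median log2 fold change of tested nuclear genes was 0.01 with TMM, -0.01 with RLE and 0.01 with nuclear genes only.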

Other observations

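The length correction, the tests of annotation terms, and the tests of chloroplast genes, of length in the seed markers, of root markers, of the U1 feature and of a length-dependent effect of the mutation were chosen after the result was seen. After length correction, 24 of 669 biological process terms in the table's annotation passed camera's adjusted threshold, and 0 did with an estimated correlation (adjusted p = 0.946 for each term named here). None of the genes named in this paragraph or the next passed over all genes. All 20 genes of the term for response to mechanical stimulus had negative length-corrected values (median log2 fold change -0.38, adjusted p = 0.00133). The touch-induced calmodulin-like gene CML12 was at 57.2 ± 52.4 CPM in the wild type and 13.3 ± 4.1 CPM in the mutant, and the wall-loosening enzyme gene XTH22 at 35.8 ± 20.3 and 14 ± 0.476 CPM (SD, n = 3 each). CML24, a calmodulin-like gene also induced by touch, had a length-corrected log2 fold change of -1.28 ± 0.44 (SE). Xyloglucan metabolic process genes were lower in 21 of 24 (median -0.52, adjusted p = 0.00399), with XTH18 at -1.69 ± 0.45 (SE) and XTH9 at -1.34 ± 0.38 (SE). These terms rested on wild-type library 1: without it their adjusted p was 0.429 and 0.879, the highest of the 6 fits with 1 library left out, and in the other 5 each term passed. Over these 6 fits the median ranged from -0.21 to -0.69 for mechanical stimulus and from -0.19 to -0.83 for xyloglucan.

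In transcription from plastid promoter, 33 of 36 genes were higher (median length-corrected log2 fold change 0.24, adjusted p = 0.000515), among them PTAC2 at 1.5 ± 0.43 (SE) and PTAC6 at 0.58 ± 0.19 (SE), both components of the plastid transcription machinery. Transition metal ion transport genes were lower in 21 of 23 (median -0.56, adjusted p = 1.23e-05), and genes of cellular response to iron ion starvation in 18 of 23 (median -0.60, adjusted p = 0.00547). The 2 metal transport members with the smallest p were annotated as a granulin-repeat protease (AT3G19390, -1.37 ± 0.32, SE) and an AT-hook protein (AHL22, -1.37 ± 0.35, SE), neither of them a transporter. Nitrate response genes were lower in 44 of 57 (median -0.28, adjusted p = 0.00552), and the nitrate transporter NPF6.3 was at -0.87 ± 0.21 (SE). Root markers were lower beside these terms (9 of 12, median -0.54), and the root hair gene RHS13 (-1.18 ± 0.44, SE) is a member of both the iron and the nitrate term. Without wild-type library 1 the adjusted p was 0.649 for plastid transcription, 0.142 for metal transport, 0.539 for iron starvation and 0.729 for nitrate response. Over the 6 fits with 1 library left out, the median stayed between -0.49 and -0.67 for metal transport and between -0.46 and -0.66 for iron starvation. It varied more for plastid transcription (0.02 to 0.39) and nitrate response (-0.07 to -0.39). In voom's quality weights wild-type library 1 received 0.233, the lowest of the 6.

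The trend of shorter genes lower and longer genes higher in the mutant could come from the libraries or from the mutation. Unequal depth is argued against, because after thinning every library to the smallest total the Spearman correlation of fold change with length was 0.578 over 6847 nuclear genes. A length-dependent difference between libraries that acts on any RNA, through RNA quality or library preparation, stays open: the 74 chloroplast-encoded protein-coding genes, which are not transcribed in the nucleus, showed the trend too (0.397 across genes). The length slopes of both genotypes do not overlap, at the smallest exact permutation p the design allows (0.1). A difference between libraries and an effect of the mutation on nuclear transcription both allow this, so the slopes cannot tell them apart. An effect limited to nuclear transcription would not directly give the chloroplast trend, but such an effect beside a general one stays open. Each slope is relative to the mean over all 6 libraries, so opposite signs in the genotypes follow in part from the calculation. The difference between genotypes carries the information, not the sign of a slope. The lower seed and the higher SNF2 groups differed in their response to the length correction, which left the first at -1.35 and the second at -0.05.

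Lower seed storage transcripts in the mutant may reflect fewer residual seed reserves or other differences between the seedling samples, a hypothesis that was not tested. Gene length is argued against as the whole cause, as the median of the 4 members stayed at -1.35 after length correction. A single wild-type library is argued against as the whole cause, although its size depends on wild-type library 1: the median was -0.90 without it, -1.69 without wild-type library 2 and -1.74 without wild-type library 3. CRC was at 41.5, 18.6 and 3.58 CPM in wild-type libraries 1, 2 and 3 and at 6.45, 8.89 and 1.59 CPM in mutant libraries 1, 2 and 3, so the groups overlapped for this gene.

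The lower value of AT4G23420 in the mutant may come from U1 small nuclear RNA reads, because the U1 gene AT4G07120 lies within its span and has no feature of its own in the table. The separate U1 feature AT1G08115 was at 5162 ± 3164 CPM in the wild type and 1137 ± 440 CPM in the mutant (SD, n = 3 each; log2 fold change -2.18 ± 0.42, SE; edgeR adjusted p = 0.0568). The AT4G23420 count relative to the AT1G08115 count lay between 18.5% and 27.9% in all 6 libraries and changed by -0.14 on the log2 scale between genotypes (exact two-sided permutation test, p = 0.5). A change of the gene's own messenger RNA would need reads outside the U1 interval, which were not analysed here.

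A smaller share of root tissue in the mutant samples is a hypothesis for lower root, iron and nitrate values and for higher photosynthesis values. Of 12 root markers with at least 20 reads in total, 9 had negative length-corrected values, with a median log2 fold change of -0.54, including the root hair genes LRX1 (-1.57) and COBL9 (-1.39), while CASP2 (0.69) and SHR (0.41) went the other way. These markers belong to the pattern to be explained and come from the same libraries, so they do not test the hypothesis separately. The root list did not pass after length correction (camera adjusted p = 0.241). Without wild-type library 1 the iron and nitrate terms did not pass (camera adjusted p = 0.539 and 0.729). Within 0.5 Mb of ATRX, 6 of 173 tested genes had an unadjusted p under 0.01 after length correction, all lower in the mutant, against a median of 4 and a 95th percentile of 9 in 10000 windows of the same size (percentile 76.1), which leaves a local effect of the mutated locus open.

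For the counts of changed genes, the 10 possible splits of 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 16 genes and the highest other split 3, so that 1 of the 10, the real split itself, reached the real count. After length correction the real split gave 4 genes and the highest other split 6, so that 3 of the 10, the real split and 2 others, reached it.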
